A study of Mus musculus with 32 samples.

How the data were processed

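Mouse embryonic fibroblasts (MEFs, connective tissue cells grown from mouse embryos) were treated with thapsigargin, a blocker of the calcium pump of the endoplasmic reticulum (ER) that empties the calcium store and causes ER stress. The 4 conditions were thapsigargin for 0 h (control), for 1 h, for 16 h, and for 16 h with an inhibitor of PERK present for the last 4 h. PERK is the ER kinase that phosphorylates the translation factor eIF2 under ER stress. Per the labels' protocols, cytosolic RNA was extracted, part of it was run on a sucrose gradient, and the fractions with mRNAs that carried more than 4 ribosomes were collected as polysome-associated RNA. TruSeq libraries were made from both kinds of RNA in 4 replicates per condition, which gives 16 samples and 32 libraries. The name and dose of the inhibitor, the dose of thapsigargin and whether the group without inhibitor received its solvent are not given in the sources used here.

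The deposited table holds raw counts per gene symbol, 20234 genes by 32 libraries, and each column was matched to its sample by the name in the sample description. Reads were aligned with HISAT to mm10, and DESeq2 1.9.23 was used, per the submitters' processing notes, which carry no version for HISAT. The counting tool, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be assigned with certainty. The deposited counts were whole numbers with totals that differed between libraries, so they had not been divided by size factors, and 3234 genes were at 0 in every library. Total counts ran from 19.32 to 41.78 M per library. Any pair of libraries of 1 group differed by more than sampling noise, the lowest chi-square per degree of freedom being 2.29 over genes with at least 10 counts, so no library was counted as a repeat of another.

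Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and edgeR's quasi-likelihood test with robust dispersion estimates was applied. Cytosolic RNA (12366 genes) and polysome RNA (12065 genes) were each fitted over their 16 libraries with the 4 conditions as groups, which left 12 residual degrees of freedom. Translational efficiency, here the ratio of polysome to cytosolic RNA of a gene, was tested over all 32 libraries (12561 genes) as the interaction of RNA kind and condition, with each sample as a block. That block rests on the series design, in which the RNA of every sample was divided into both kinds. Deviations of the cytosolic and polysome library of a sample from their group means had a median correlation of 0.0542 over genes, with a range of -0.316 to 0.16. The 4 comparisons were made with each measure: 1 h against control, 16 h against control, 16 h against 1 h, and the inhibitor group against 16 h without inhibitor. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Errors of log2 changes are standard errors (SE) from the fit, and errors of levels in CPM (counts scaled to library size with TMM factors) are standard deviations (SD) over 4 libraries. Levels were scaled with factors computed over all 32 libraries, and changes in cytosolic or polysome RNA with factors computed over the 16 libraries of that kind. Ratios of printed levels therefore differ somewhat from the printed folds. The labels do not say that the 4 replicates were separate cultures or isolates, so p-values measure the spread between these samples, which may be technical. Because each library is scaled to its own total, a loss of polysomes common to all mRNAs is not visible, and every change is relative to the other mRNAs of the same library.

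Named genes followed a rule: 14 panel genes of the ER stress response in every comparison, and the 4 genes with the highest and the 4 with the lowest log2 change in cytosolic RNA and in translational efficiency among called genes. These extremes needed a mean of at least 5 CPM and conditions whose libraries did not overlap, and clone-type symbols were left out. Up to 3 members of each called list and up to 2 of other lists, those with the smallest p, complete the rule. Besides the panel, 37 gene lists were fixed: targets of the transcription factors ATF4 and CHOP, tRNA synthetases, amino acid transport, serine metabolism, 5 lists of ER functions, mRNAs with regulatory upstream open reading frames, ribosomal proteins and other mRNAs with terminal oligopyrimidine (TOP) starts, 3 lists of initiation factors, 3 of mitochondrial genes, cholesterol synthesis, 3 of signalling responses (immediate early, NF-kB and p53), 2 of the cell cycle, matrix, heat shock, NRF2 targets, autophagy, glycolysis, proteasome, nuclear-retained RNAs and 6 lists of markers of other cell types. Lists were compared with all other genes by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, then again with an estimated correlation. Lists with at least 3 tested members were tested, which left 33. Groups, tests, named-gene rule, lists and most alternatives were set before the data were examined. The text prints only a part of the genes that the rule names.

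The fit was tested on simulated counts, with 50 genes changed at 1 h at each of 4 sizes. Means came from the control libraries, dispersions from all 4 conditions, and each library kept its own depth. Genes were drawn independently, so shifts that many genes of a library share are absent and the shares called may be too high. For cytosolic RNA at 1 h, 20%, 72%, 84% and 100% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale were called with the right sign. For polysome RNA at 1 h the shares were 22%, 64%, 94% and 100%, and for translational efficiency at 1 h they were 6%, 56%, 86% and 96%. Depth was lowest at 1 h, where cytosolic libraries held 19.32 to 34.76 M counts.

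Gene coordinates, coding lengths and GC content come from the GENCODE M21 annotation of GRCm38 (mm10), matched by symbol. Alternatives tried were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0, no low-count filter, a mean of at least 10 CPM, fits on only the conditions compared, the replicate number as a block, no sample block, an analysis of partial variance for translational efficiency, an estimated correlation and fry for the lists, and each sample left out in turn. Offsets corrected for GC content or for coding length (splines with 5 degrees of freedom), and a fit without the 2 shallower samples at 1 h, were added after the data had been seen. For comparisons that share libraries, 20 simulations of unchanged groups gave the correlation expected without effects, and the shared libraries were also divided 2 and 2. Figures were drawn with matplotlib 3.10.9. Mitochondrially encoded genes had no symbol in the table and nuclear-retained RNAs were represented by 1 gene, so RNA quality and nuclear carry-over were not analysed here through those lists.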

Results

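Gene expression was measured in mouse embryonic fibroblasts (MEFs, connective tissue cells grown from mouse embryos) in 4 conditions: control, thapsigargin for 1 h, thapsigargin for 16 h, and thapsigargin for 16 h with an inhibitor of the kinase PERK during the last 4 h. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER) and causes ER stress. Each of the 16 samples gave a library of cytosolic RNA and a library of polysome RNA, the mRNAs that carried more than 4 ribosomes. Control libraries held 28.28 to 31.98 M counts in cytosolic RNA and 30.74 to 35.64 M in polysome RNA. At 1 h the ranges were 19.32 to 34.76 and 21.16 to 34.68 M, the widest of the 4 conditions. Libraries at 16 h held 29.47 to 34.97 M counts (cytosolic) and 33.36 to 36.22 M (polysome), and those with the inhibitor 33.54 to 34.91 and 35.72 to 41.78 M. The 10 most abundant genes took 4.56% of the counts in control cytosolic libraries and 11.6% in polysome libraries at 16 h. Translational efficiency denotes the ratio of polysome to cytosolic RNA of a gene. All folds rest on 4 replicates per condition, and all changes are relative to the other mRNAs of the same libraries.

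A panel of 14 genes of the ER stress response was followed in each comparison. Its main members lie, on GRCm38 (mm10), on chromosome 15 from 80255184 to 80257541 (Atf4), chromosome 7 from 45522916 to 45526268 (Ppp1r15a), chromosome 2 from 34771970 to 34777547 (Hspa5), chromosome 8 from 94386438 to 94395377 (Herpud1) and chromosome 6 from 7675169 to 7693254 (Asns). Atf3 lies on chromosome 1 from 191170296 to 191218039, Slc7a11 on chromosome 3 from 49892526 to 50443614, and Ddit3, which has 2 loci in the annotation, on chromosome 10 from 127290829 to 127293753. Each is a protein-coding gene in that annotation, and which parts of it the deposited counts cover is not given. Of 168 tests of panel genes, all but 25 were called. In 140 of the calls the 4 values of a condition lay entirely to one side of the 4 values of the other. The exceptions were Ppp1r15b at 16 h against 1 h, in both kinds of RNA, and the translational efficiency of Chac1 at 16 h against control. Such separation was counted only among calls made on the same libraries, so it adds no independent evidence. The 2.86% of splits of 4 and 4 that chance gives holds for an unselected test and not for these calls.

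The comparison of 1 h with control addresses the acute response to ER stress. Ddit3, which encodes the transcription factor CHOP, rose in cytosolic RNA from 13.6 ± 2.22 to 92.5 ± 5.72 CPM (SD, n = 4), 6.72-fold. Hspa5, which encodes the ER chaperone BiP, rose 3.06-fold, Atf3, a stress-induced transcription factor, 3.03-fold, and Herpud1, a component of ER-associated degradation, 2.13-fold. Atf4, the transcription factor whose translation is raised when eIF2 is phosphorylated, rose 1.42-fold (log2 change 0.51 ± 0.0326 SE). Ppp1r15a, the induced subunit of the eIF2 phosphatase, rose 1.71-fold, while Ppp1r15b, its constitutive counterpart, fell 1.79-fold and Eif2ak3, which encodes PERK, fell 1.17-fold. Dnajb9, Xbp1 and the cystine transporter gene Slc7a11 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 0.695, 0.271 and 0.0968. The highest changes among genes with at least 5 CPM were those of the immediate early genes Ier2 (8.44-fold) and Fos (7.78-fold), of Txnip, a thioredoxin-binding protein (6.79-fold), and of Ddit3. The lowest were those of Oaf (3.66-fold lower), Fam134c, an ER-phagy receptor (3.39-fold lower), the phosphatase gene Dusp2 (3.14-fold lower) and Lfng, a glycosyltransferase acting on Notch (3.07-fold lower).

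Of 28 immediate early genes, which respond first to growth and stress signals, 27 rose at 1 h and none fell, among them Egr2 (6.3-fold), Dusp1 (4.92-fold) and Egr1 (4.89-fold). All 20 cytosolic aminoacyl-tRNA synthetase genes rose, including Tars (2.07-fold) and Aars (2.01-fold), as did 12 of 13 genes of serine and one-carbon metabolism and all 12 eIF3 subunits. Among ATF4 and CHOP target genes 21 of 32 rose and 4 fell, among NF-kB and inflammatory genes 12 of 19 rose and 3 fell (Tnfaip3, a feedback inhibitor of NF-kB, 3.04-fold higher), and among cytosolic heat shock genes 15 of 18 rose. DNA replication genes rose in 18 of 28 cases and fell in 4. Genes of ER translocation and N-glycosylation moved the other way, 27 of 33 falling and 2 rising; Dad1, a subunit of oligosaccharyltransferase, fell 2.41-fold. ER calcium handling genes fell in 13 of 19 cases and rose in 3. Adjusted over the list alone, 27, 20, 13, 12, 25, 15, 16, 22, 30 and 17 members of these lists were called. These 10 lists were called by camera with adjusted p from 1.53e-25 (immediate early genes) to 0.000307 (DNA replication), and all held with an estimated correlation. Calls lost with an estimated correlation were those of mitosis and G2/M genes (19 of 25 rose and 4 fell, adjusted p = 0.151 with an estimated correlation) and of fibroblast extracellular matrix genes (20 of 33 rose and 7 fell, adjusted p = 0.101 with an estimated correlation). The same held for ER chaperones and folding enzymes, of which 14 of 25 fell and 5 rose (adjusted p = 0.33 with an estimated correlation), and for ER-associated degradation, of which 11 of 22 fell and 6 rose (adjusted p = 0.0541 with an estimated correlation). Proteasome genes rose in 22 of 31 cases and fell in 4, other mRNAs with terminal oligopyrimidine (TOP) starts rose in 12 of 19 and fell in 1, glycolysis and hypoxia genes rose in 11 of 19 and fell in 3, and ER to Golgi transport genes fell in 16 of 32 and rose in 15. Their calls were lost too (adjusted p = 0.234, 0.33, 0.202 and 0.33 with an estimated correlation). Ribosomal protein genes were not called as a list (25 of 79 higher, 8 lower). In all, 6955 of 12366 genes were called in cytosolic RNA, 3476 higher and 3479 lower, and 259 and 321 of them changed at least 2-fold.

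**Figure D1:**
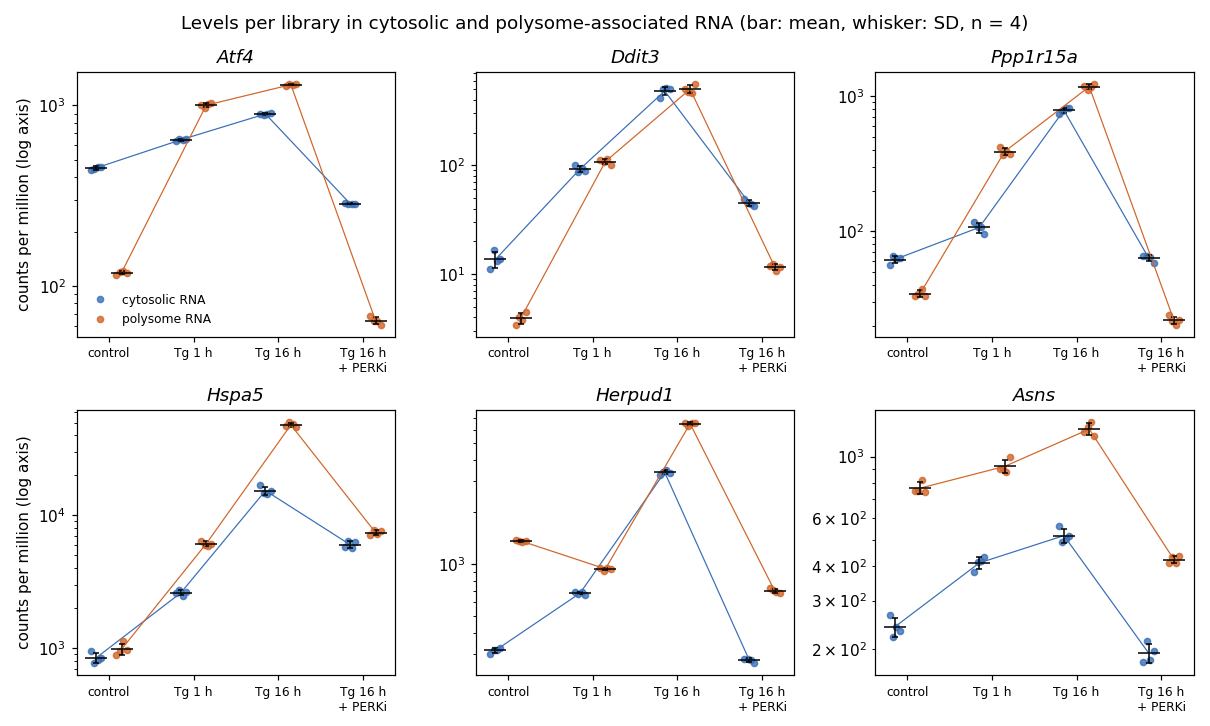
Levels of 6 stress response genes per library, in CPM on a log axis, for the 4 conditions in cytosolic and polysome RNA; points are libraries, and bars give the mean and SD (n = 4). Atf4 in polysome RNA rose from a mean of 118.6 CPM in control to 1003 CPM at 1 h and lay at 64.2 CPM with the PERK inhibitor.

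In polysome RNA the changes at 1 h were wider. Atf4 rose from 118.6 ± 2.51 to 1003 ± 23.3 CPM (SD, n = 4), 8.78-fold, and its log2 ratio of polysome to cytosolic RNA went from -1.93 ± 0.0257 to 0.64 ± 0.036, a 5.91-fold rise in translational efficiency. Ddit3 rose 28.6-fold in polysome RNA and 4.05-fold in translational efficiency, and Ppp1r15a 11.7-fold and 6.52-fold. Translational efficiency also rose for Slc7a11 (2.13-fold) and Hspa5 (2.02-fold). It fell for Herpud1 (3.12-fold), whose polysome RNA fell 1.4-fold although its cytosolic RNA rose, and for Trib3, a pseudokinase induced by ATF4 and CHOP (2.7-fold), Xbp1 (1.92-fold), Dnajb9 (1.89-fold), Eif2ak3 (1.54-fold), Chac1, a glutathione-degrading enzyme (1.53-fold), Atf3 (1.51-fold) and Asns, asparagine synthetase (1.43-fold). Ppp1r15b did not pass the test for translational efficiency (log2 change -0.14 ± 0.096 SE). Among the highest changes in translational efficiency were those of the zinc finger gene Zfp157 (10.3-fold), Son, a splicing cofactor (9.9-fold), and Map1b, a microtubule-associated protein (9.78-fold). The lowest belonged to Lgals3, which encodes galectin-3 (5.94-fold lower), the reductase gene Blvrb (5.91-fold lower), the ribosomal protein gene Rpl6 (5.27-fold lower) and the tropomyosin gene Tpm2 (5.11-fold lower).

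Among 21 mRNAs with upstream open reading frames known to be translated under eIF2 phosphorylation, translational efficiency rose for 14 and fell for 5 at 1 h; Eprs, a tRNA synthetase, rose 4.11-fold. Cytosolic ribosomal protein mRNAs fell in 58 of 79 cases and rose in 3, with a list median of -1.18, and proteasome subunits fell in 30 of 31 cases and rose in 1, with a median of -1.37. Psmb3, a subunit of the proteasome core, fell 3.95-fold. Among eIF3 subunits 9 of 12 fell and 2 rose, with Eif3a 5.83-fold higher; among glycolysis and hypoxia genes 12 of 19 fell and 4 rose. Fibroblast extracellular matrix mRNAs rose in 17 of 34 cases and fell in 7, Thbs1, which encodes thrombospondin-1, rising 5.88-fold and the tenascin gene Tnc 6.2-fold. Adjusted over the list alone, 19, 62, 31, 11, 16 and 25 members were called. All 6 lists were called by camera, with adjusted p from 1.02e-18 (proteasome) to 0.00164 (glycolysis), and held with an estimated correlation. Calls of 8 further lists, each lower, were lost with an estimated correlation. Among them, other TOP mRNAs fell in 16 of 19 cases (adjusted p = 0.174 with an estimated correlation) and nuclear-encoded respiratory chain mRNAs in 34 of 56 (adjusted p = 0.151 with an estimated correlation). ER chaperones fell in 20 of 25 cases (adjusted p = 0.304 with an estimated correlation), cholesterol synthesis mRNAs in 18 of 23 (adjusted p = 0.151 with an estimated correlation) and autophagy and lysosome mRNAs in 16 of 27 (adjusted p = 0.174 with an estimated correlation). Values of ribosomal proteins are uncertain for single genes, since reads can be shared with processed pseudogenes. Changes in translational efficiency at 1 h went with coding length, with a median log2 change of 0.43 for coding sequences under 400 nt (514 genes), -0.42 for 600 to 900 nt (1650 genes) and 0.88 for those over 3000 nt (1729 genes). With offsets corrected for coding length, the log2 changes of Son, Map1b and Eprs were 2.05, 2.03 and 1.22, against 3.31, 3.29 and 2.04 without it, and Chac1 no longer passed the test (-0.29). In an analysis of partial variance, which takes the cytosolic level as a covariate, Chac1, Atf3, Trib3 and Asns turned to 1.43, 0.31, 0.19 and 0.17. The slope on that level had a median of -0.0255, with 6934 of 12561 genes under 0. This median does not give the size of single slopes, so it does not tell how much of the cytosolic change was subtracted for these genes. In polysome RNA itself 20 of 33 lists were called, and 1, the mRNAs with upstream open reading frames, held with an estimated correlation. Of 12065 genes in polysome RNA 9597 were called, 2194 at least 2-fold higher and 1692 at least 2-fold lower; of 12561 tested for translational efficiency 8512 were called, 1890 and 1503 at least 2-fold.

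After 16 h of thapsigargin, the comparison with control addresses the chronic response. In cytosolic RNA Ddit3 rose to 483 ± 43.5 CPM (SD, n = 4), 32.5-fold over control, Hspa5 16.7-fold, Atf3 13.1-fold, Ppp1r15a 11.7-fold, Chac1 11.4-fold, Herpud1 9.9-fold and Dnajb9, an ER cochaperone, 7.45-fold. Xbp1, a transcription factor of the unfolded protein response, rose 2.11-fold, Asns 1.98-fold, Atf4 1.83-fold and Eif2ak3 1.54-fold. Ppp1r15b fell 2.26-fold, and Slc7a11 did not pass the test (log2 change -0.04 ± 0.0847 SE). Genes close to the detection floor in control reached moderate levels, and their levels are given in place of folds: Sspo went from 0.405 ± 0.278 to 73.0 ± 19.1 CPM, Ifi44, an interferon-induced gene, from 0.407 ± 0.179 to 38.2 ± 3.37, B4galnt2, a glycosyltransferase, from 0.127 ± 0.0583 to 14.04 ± 1.18, and Ostn, which encodes osteocrin, from 0.103 ± 0.0933 to 12.8 ± 1.09. In the other direction Egr3, an immediate early transcription factor, went from 280.4 ± 7 to 0.424 ± 0.131 CPM, Dpt, a matrix protein gene, from 55.7 ± 2.9 to 0.411 ± 0.0905, the endocan gene Esm1 from 14.2 ± 0.956 to 0.0723 ± 0.0697 and the protease gene Prss46 from 5.26 ± 0.396 to 0.0131 ± 0.0262.

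ER chaperones and folding enzymes rose in 20 of 25 cases at 16 h and fell in 3, among them Hyou1 (7.76-fold) and Pdia6 (4.76-fold). ATF4 and CHOP target genes rose in 25 of 32 cases and fell in 4 (Ndrg1 5.88-fold, Got1 4.28-fold), aminoacyl-tRNA synthetases rose in 18 of 20 and fell in 2 (Wars 5.85-fold higher), serine and one-carbon metabolism rose in 11 of 13 and fell in 1, ER-associated degradation rose in 15 of 22 and fell in 5, and mitochondrial chaperones and proteases rose in 10 of 13 and fell in 3 (the protease gene Lonp1 3.03-fold higher). Fibroblast extracellular matrix genes fell in 27 of 33 cases and rose in 1; Thbs1 fell 45.7-fold and Timp2, a metalloproteinase inhibitor, 11.7-fold. All 25 genes of mitosis and G2/M fell, the cyclin gene Ccnb2 12.8-fold, and 23 of 28 immediate early genes fell while 3 rose, with Cyr61 25.6-fold and Ctgf 88.3-fold lower. Cholesterol synthesis genes fell in 21 of 23 cases and rose in 1, and NF-kB and inflammatory genes fell in 13 of 19 and rose in 3. Adjusted over the list alone, 23, 30, 20, 12, 20, 13, 28, 25, 26, 22 and 16 members were called. These 11 lists were called by camera, with adjusted p from 5.99e-27 (immediate early genes) to 0.0049 (mitochondrial chaperones), and held with an estimated correlation. ER translocation and N-glycosylation genes rose in 26 of 33 cases and fell in 5, a call lost with adjusted p = 0.276 with an estimated correlation, and ER to Golgi transport genes rose in 25 of 32 and fell in 6 (adjusted p = 0.167 with an estimated correlation). Ribosomal protein genes rose in 50 of 79 cases and fell in 5 (adjusted p = 0.304 with an estimated correlation). Among ER calcium handling genes, not called as a list, the pump gene Atp2a3 went from 0.72 ± 0.0874 to 28.2 ± 2.57 CPM. In cytosolic RNA 9559 genes were called, 4683 higher and 4876 lower, with 1033 and 2171 at least 2-fold.

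In polysome RNA at 16 h Ddit3 rose by 6.92 on the log2 scale, from 3.92 ± 0.443 to 502 ± 43.6 CPM (SD, n = 4), Hspa5 46.4-fold, Ppp1r15a 32.4-fold, Hsp90b1, an ER chaperone, 25.7-fold, and Atf4 10.5-fold. Translational efficiency rose for Atf4 (5.52-fold), Ddit3 (3.6-fold), Hspa5 (2.7-fold), Ppp1r15a (2.68-fold) and Slc7a11 (2.07-fold), and fell for Trib3 (2.47-fold), Herpud1 (2.26-fold), Dnajb9 (1.57-fold), Chac1 (1.51-fold) and Eif2ak3 (1.46-fold). The highest changes in translational efficiency were those of Avil, an actin-binding protein gene (14.1-fold), the nucleoporin gene Ranbp2 (9.36-fold), Bclaf1 (7.81-fold) and Simc1 (7.75-fold). Nr4a1, an orphan nuclear receptor gene, had a large fall (8.06-fold), as its polysome RNA went from 487.9 ± 78.3 to 2.12 ± 0.145 CPM and its cytosolic RNA from 130.7 ± 28.7 to 4.62 ± 1.17. Pcyox1l fell 5.99-fold and the matrix gene Vwa1 5.17-fold. Translational efficiency of mRNAs with upstream open reading frames rose in 13 of 21 cases and fell in 4, and that of matrix mRNAs rose in 21 of 34 and fell in 6 (the fibronectin gene Fn1 4.41-fold higher). It fell for 64 of 79 ribosomal protein mRNAs and rose for 1, with a list median of -1.23, and fell for 27 of 31 proteasome mRNAs and rose for 1, with a median of -1.13. Adjusted over the list alone, 17, 28, 68 and 28 members were called, and these lists were called by camera with adjusted p from 8.19e-24 (ribosomal proteins) to 2.52e-05 (matrix) and held with an estimated correlation. Aminoacyl-tRNA synthetases rose in 11 of 20 cases and fell in 3 (adjusted p = 0.371 with an estimated correlation; the call also ended with offsets corrected for coding length), and ER chaperones, whose RNA rose, fell in translational efficiency in 16 of 25 cases and rose in 4 (adjusted p = 0.45 with an estimated correlation). With offsets corrected for coding length, Ranbp2, Simc1 and Fn1 changed by 2.00, 2.23 and 1.04 on the log2 scale, against 3.23, 2.95 and 2.14 without it, and Dnajb9 and Chac1 no longer passed the test (-0.26 and -0.21). By the analysis of partial variance Herpud1, Trib3, Dnajb9, Chac1, Eif2ak3 and Thbs1 turned direction, to 1.66, 0.79, 2.71, 2.55, 0.16 and -1.89. In polysome RNA 10273 genes were called, 2443 at least 2-fold higher and 2690 at least 2-fold lower, and in translational efficiency 8061, with 1670 and 1216. The 2886 calls of translational efficiency at 2-fold or more became 4890 by the analysis of partial variance.

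**Figure D2:**
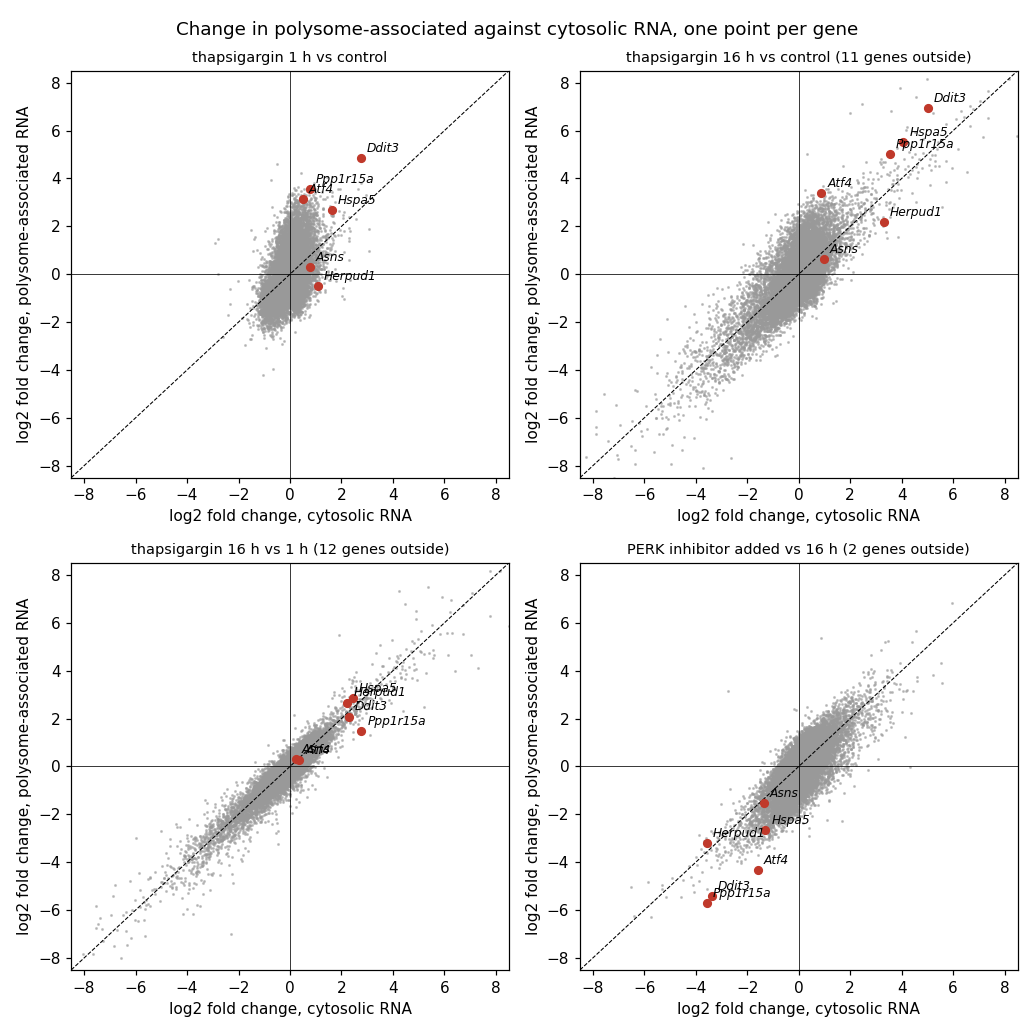
Log2 change of each gene in polysome RNA (vertical axis) against its log2 change in cytosolic RNA (horizontal axis) in the 4 comparisons, with 6 stress genes named and the line of equal change dashed; each point is a gene. The correlation across genes was lowest at 1 h (r = 0.429) and highest for 16 h against 1 h (r = 0.949).

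The direct comparison of 16 h with 1 h separates later from early changes. In cytosolic RNA Dnajb9 rose 7.65-fold from 1 h to 16 h, Ppp1r15a 6.8-fold, Hspa5 5.45-fold, Ddit3 4.84-fold and Herpud1 4.65-fold, while Atf4 rose 1.29-fold and Asns 1.17-fold. Trib3 and Slc7a11 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 0.0525 and 0.177. Car6, a secreted carbonic anhydrase gene, went from 1.71 ± 0.145 to 124.8 ± 7.94 CPM (SD, n = 4), whereas Egr2 went from 181.9 ± 5.56 to 0.237 ± 0.017, Fos from 163.2 ± 8.73 to 0.457 ± 0.151 and Arc, another immediate early gene, from 118.7 ± 15.1 to 0.518 ± 0.117. ER chaperones rose in 24 of 25 cases and none fell (Sdf2l1 10.5-fold, Manf 9.14-fold), ER translocation and N-glycosylation rose in 32 of 33 and fell in 1, and ER-associated degradation rose in 16 of 22 and fell in 1. Immediate early genes fell in 25 of 28 cases and rose in 1, mitosis genes in 25 of 25, matrix genes in 29 of 33 with 1 rise (Thbs1 83.8-fold lower), DNA replication genes in 21 of 28 with 5 rises, and cholesterol synthesis genes in 20 of 23 with none rising. Counted as adjusted over the list alone, 24, 33, 17, 27, 25, 30, 26 and 20 members were called. All of these lists were called by camera, with adjusted p from 2.32e-54 (immediate early genes) to 0.00479 (DNA replication), and held with an estimated correlation. Autophagy and lysosome genes rose in 18 of 27 cases and fell in 6 (Sqstm1, an autophagy receptor gene, 2.4-fold higher), with adjusted p = 0.125 with an estimated correlation.

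Translational efficiency differed less between 16 h and 1 h than from control, with 3527 of 12561 genes called, 35 at least 2-fold higher and 78 at least 2-fold lower, against 9316 called in cytosolic and 9467 in polysome RNA. By the analysis of partial variance 7306 genes were called, and Ppp1r15a, Steap4 and Hsd17b7 turned to 0.735, -3.77 and -0.42. With offsets corrected for GC content 5589 genes were called, and without the 2 shallower samples at 1 h, left out after the data had been seen, 1851 genes were called. Ppp1r15a fell 2.43-fold in translational efficiency, while Xbp1 rose 1.45-fold, Herpud1 1.38-fold, Hspa5 1.34-fold and Atf3 1.25-fold; Atf4 (log2 change -0.10 ± 0.0504 SE) and Ddit3 (-0.17 ± 0.0918) did not pass the test. Avil rose 5.01-fold, the metalloreductase gene Steap4 2.75-fold and Pdlim5 2.26-fold, and Ogt, which encodes O-GlcNAc transferase, fell 3.73-fold and the amine oxidase gene Aoc3 2.76-fold. Cholesterol synthesis mRNAs rose in 18 of 23 cases with none falling (Hsd17b7 1.6-fold), glycolysis and hypoxia mRNAs rose in 12 of 19 and fell in 1, and cytosolic heat shock mRNAs rose in 8 of 18 with none falling (Dnajb1 1.59-fold). Of these lists 18, 15 and 8 members were called when adjusted over the list alone, and camera called these lists with adjusted p of 1.57e-09, 2.85e-06 and 3.39e-05, each held with an estimated correlation. Proteasome mRNAs rose in 19 of 31 cases (adjusted p = 0.174 with an estimated correlation), and ribosomal protein mRNAs fell in 17 of 79 (adjusted p = 0.445 with an estimated correlation), a call that also ended with offsets corrected for coding length. NRF2 target mRNAs rose in 6 of 19 cases and fell in 1 (adjusted p = 0.206 with an estimated correlation).

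The comparison of the inhibitor group with 16 h of thapsigargin alone asks which parts of the chronic response change when PERK is blocked late. In cytosolic RNA Atf3 fell 53.5-fold, Chac1 30.2-fold, Trib3 15.8-fold, Ppp1r15a 11.9-fold, Herpud1 11.8-fold, Ddit3 10.4-fold and Slc7a11 9.07-fold. Atf4 fell 3.03-fold, from 898 ± 6.39 to 286 ± 2.15 CPM (SD, n = 4), Asns 2.57-fold, Ppp1r15b 2.48-fold, Hspa5 2.46-fold, Dnajb9 2.14-fold and Xbp1 1.91-fold, and Eif2ak3 did not pass the test (log2 change 0.03 ± 0.0442 SE). Cass4, a docking protein gene, went from 15.3 ± 0.781 to 0.0834 ± 0.0723 CPM, Fgf21, a stress-induced hormone gene, from 17.99 ± 2.97 to 0.427 ± 0.167, and Fibin from 9.48 ± 1 to 0.254 ± 0.0778. Among genes that rose, Bmf, a proapoptotic BH3-only gene, went from 0.959 ± 0.0463 to 14.2 ± 1.01 CPM, the scaffold gene Mpp2 rose 14.9-fold and Mrgprf 13-fold. The heat shock gene Hspa1b went from 0.896 ± 0.355 to 14.3 ± 2.78 CPM, a value that is uncertain because reads can be shared with its near-identical neighbour Hspa1a.

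ATF4 and CHOP target genes fell in 27 of 32 cases with the inhibitor and rose in 4 (Gpt2, an alanine aminotransferase, 5.41-fold lower), aminoacyl-tRNA synthetases fell in 19 of 20 and rose in 1 (Cars 5.4-fold lower), serine and one-carbon metabolism fell in 12 of 13 with none rising (Aldh18a1 4.52-fold lower), and amino acid transporters fell in 12 of 15 and rose in 2 (Slc7a1 5.62-fold lower). Among mRNAs with upstream open reading frames 13 of 21 fell and 6 rose, and among mitochondrial chaperones 8 of 13 fell and 1 rose. DNA replication genes rose in 24 of 28 cases and fell in 2 (E2f2 9.8-fold higher), mitosis genes rose in 23 of 25 and fell in 1 (Aurkb 3.97-fold higher), and heat shock genes rose in 14 of 18 and fell in 2 (Hspa8 3.77-fold higher). Adjusted over the list alone, 31, 20, 12, 14, 19, 9, 26, 24 and 17 members were called. These 9 lists were called by camera, with adjusted p from 6.25e-32 (ATF4 and CHOP targets) to 0.00681 (mitochondrial chaperones), and held with an estimated correlation. ER chaperones were not called as a list, with 8 of 25 higher and 13 lower. Ribosomal protein genes rose in 71 of 79 cases with none falling (adjusted p = 0.421 with an estimated correlation), and respiratory chain genes rose in 43 of 56 and fell in 6 (adjusted p = 0.232 with an estimated correlation); both calls also ended with offsets corrected for coding length. Genes of eIF2, eIF2B and their kinases and phosphatases fell in 11 of 17 cases and rose in 4 (adjusted p = 0.232 with an estimated correlation), and those of eIF4F, eIF1 and regulators fell in 11 of 17 and rose in 3 (adjusted p = 0.0833 with an estimated correlation). In cytosolic RNA 9239 genes were called, 5223 higher and 4016 lower, with 1590 and 947 at least 2-fold, and the median of all genes lay at 0.10 on the log2 scale.

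In polysome RNA Atf3 fell 77.3-fold with the inhibitor, Ppp1r15a 52.4-fold, Ddit3 42.3-fold and Atf4 19.9-fold, to 64.2 ± 2.98 CPM (SD, n = 4) against 118.6 ± 2.51 in control. Translational efficiency fell for Atf4 (6.47-fold, the largest fall among genes with at least 5 CPM), Ppp1r15a (4.33-fold), Ddit3 (4.01-fold), Hspa5 (2.53-fold), Ppp1r15b (1.7-fold), Slc7a11 (1.63-fold) and Atf3 (1.42-fold), and rose for Dnajb9 (1.76-fold), Herpud1 (1.32-fold) and Xbp1 (1.3-fold). Asns did not pass the test (log2 change -0.16 ± 0.0778 SE). Atad2, a chromatin ATPase gene, fell 5.85-fold and the laminin gene Lamb2 5.08-fold, while the kinase gene Csnk1a1 rose 3.4-fold, Gnas, a G protein gene, 3.25-fold, Bphl 3.18-fold and the DNA repair gene Rad23b 3.17-fold. Translational efficiency of mRNAs with upstream open reading frames fell in 14 of 21 cases and rose in 1, and that of matrix mRNAs fell in 24 of 34 and rose in 4 (Thbs1 3.61-fold lower). Of these 15 and 28 were called when adjusted over the list alone, and camera called both, with adjusted p of 3.29e-08 and 8.03e-07, held with an estimated correlation. Proteasome mRNAs rose in 24 of 31 cases and fell in 2 (Psmb3 2.69-fold higher), with adjusted p = 0.0787 with an estimated correlation, and aminoacyl-tRNA synthetases fell in 14 of 20 and rose in 1 (adjusted p = 0.287 with an estimated correlation). Ribosomal protein mRNAs were not called as a list, 20 of 79 being higher and 11 lower, with a median of 0.07. With offsets corrected for coding length, Atad2 and Lamb2 changed by -1.82 and -1.50 on the log2 scale, against -2.55 and -2.34 without it, and Xbp1 no longer passed the test (0.059); by the analysis of partial variance Herpud1, Dnajb9, Xbp1 and Thbs1 turned to -2.59, -0.46, -0.68 and 0.62. DNA replication mRNAs, whose cytosolic RNA rose, fell in translational efficiency in 17 of 28 cases and rose in 7 (adjusted p = 0.122 with an estimated correlation). In polysome RNA 9995 genes were called, 1976 at least 2-fold higher and 2347 at least 2-fold lower, and in translational efficiency 7550, with 389 and 1593. The 1982 calls of translational efficiency at 2-fold or more became 1023 with the coding length correction and 4151 by the analysis of partial variance.

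**Figure D3:**
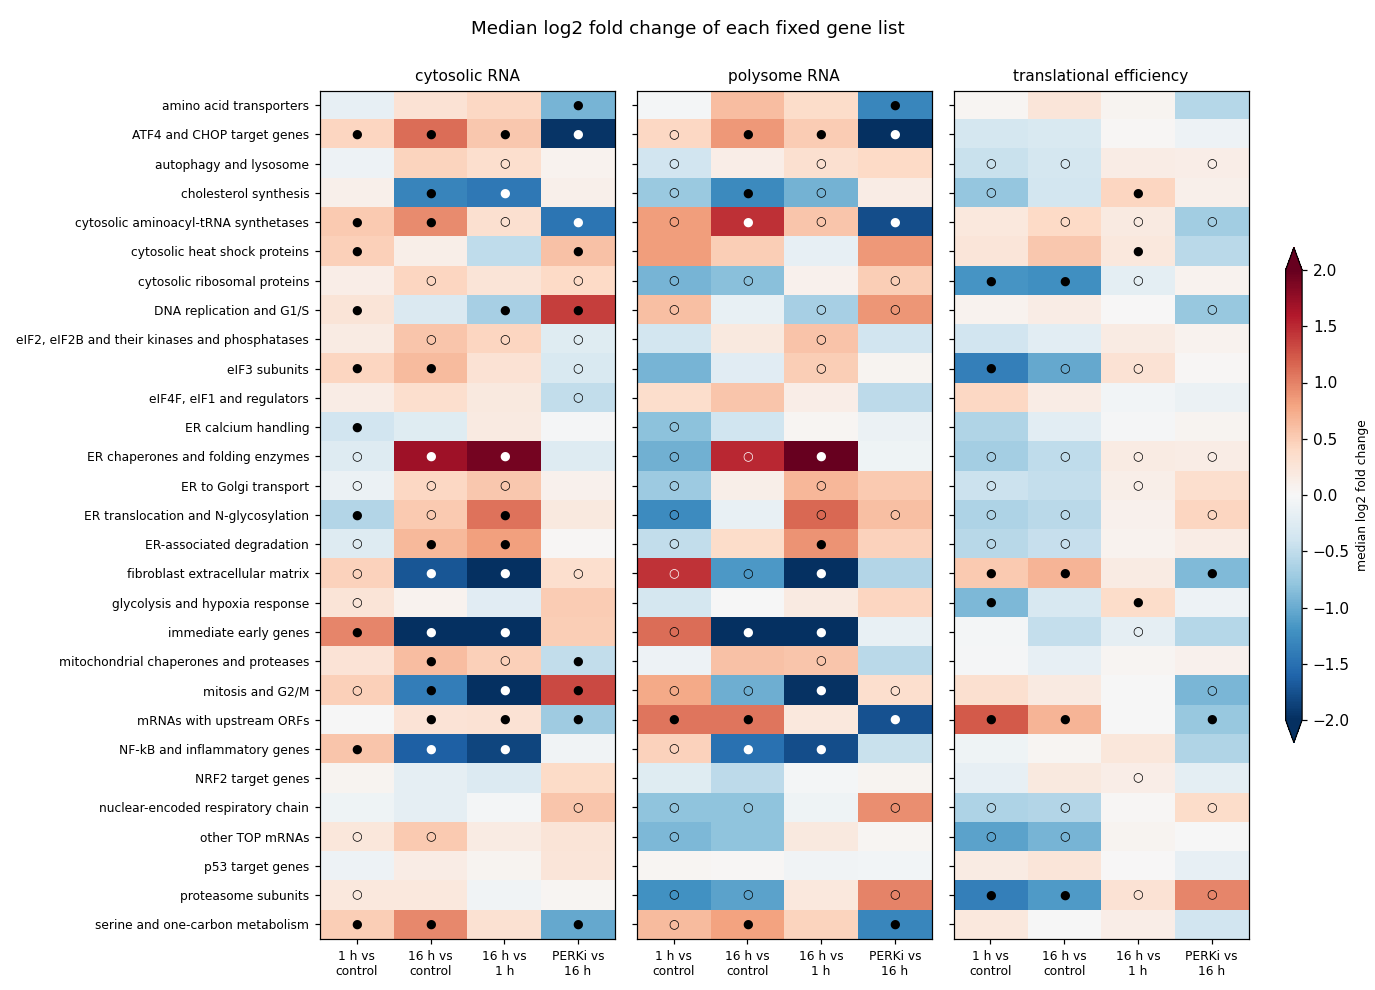
Median log2 change of the fixed gene lists in cytosolic RNA, polysome RNA and translational efficiency for the 4 comparisons, coloured from -2 to 2. Filled dots mark lists called by camera that held with an estimated correlation, open dots lists called with the preset correlation alone; ribosomal proteins and proteasome subunits had medians of -1.18 and -1.37 in translational efficiency at 1 h.

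Across 11955 genes, changes in polysome and cytosolic RNA correlated at r = 0.429 (Spearman's rho 0.375) at 1 h, 0.82 (0.712) at 16 h, 0.949 (0.908) between 16 h and 1 h, and 0.783 (0.738) for the inhibitor; genes are not independent replicates, so no p is given. Of genes called in both kinds of RNA, 1897 of 5926 went in opposite directions at 1 h, 1461 of 8242 at 16 h, 265 of 7923 between 16 h and 1 h, and 1074 of 7949 with the inhibitor. The SD of log2 changes over genes at 1 h was 0.494 in cytosolic RNA and 1.04 in polysome RNA, against 1.24 and 1.53 at 16 h.

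Changes in translational efficiency at 1 h and 16 h, both against the same control libraries, correlated at r = 0.908 across 12561 genes. Simulated unchanged groups gave 0.487, and with the control samples divided 2 and 2 between the comparisons r was 0.834. The covariance was 0.721 against 0.025 in the simulation. Of 1890 genes that rose at least 2-fold in translational efficiency at 1 h, 1722 (91.1%) also rose at 16 h; over all calls 3388 genes rose in both and 3575 fell in both, where independent lists, without shared controls, would share 1306 and 1427. In cytosolic RNA the corresponding r was 0.27 (simulated 0.494, divided controls 0.238) with a covariance of 0.153 against 0.012, and in polysome RNA 0.593 (0.477, 0.573) with 0.865 against 0.013. The simulated r stems from noise alone, so an observed r below it does not mean less agreement than without effects. The covariances and the values with divided controls are the ones to compare.

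Changes with the inhibitor and changes at 16 h share the 16 h libraries and were inversely related. In translational efficiency r was -0.811 (simulated -0.502, divided libraries -0.712), with a covariance of -0.489 against -0.026. Of 1670 genes with translational efficiency at least 2-fold higher at 16 h, 1534 (91.9%) fell with the inhibitor, and of 1216 at least 2-fold lower, 930 (76.5%) rose. In cytosolic RNA r was -0.643 (simulated -0.504, divided -0.617), with a covariance of -0.647 against -0.013; 783 of the 1033 genes at least 2-fold higher at 16 h fell, and 1625 of the 2171 at least 2-fold lower rose. In polysome RNA r was -0.732 (-0.498, -0.716), and 2185 of 2443 and 2116 of 2690 genes went the opposite way. Over all polysome calls 3853 genes rose at 16 h and fell with the inhibitor, and 3826 fell and then rose. Independent lists, without shared libraries, would share 2077 and 2179. No group received the inhibitor without thapsigargin, so a return of the response cannot be told apart from an effect of the inhibitor itself. Scaling by library totals in place of TMM moved the median of all genes in translational efficiency from -0.01 to 0.16 at 1 h, from -0.04 to 0.11 at 16 h and from -0.09 to 0.06 with the inhibitor, where 4239 genes were then called higher and 3481 lower against 3317 and 4233.

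Lists of markers of other cell types were not called in any of the 12 combinations of measure and comparison. Endothelial markers had 5 tested members, of which the highest group mean for Erg was 3.16 CPM. Macrophage and leukocyte markers had 4, with Cd14 reaching 27.9 CPM and Lyz2 3.32 CPM. Neural markers reached 146.4 CPM for Nes, which encodes nestin, 46.4 for Map2 and 31.1 for Tubb3, and muscle markers 27.6 for Acta1. Among these markers Nes fell 4.22-fold and Map2 3.32-fold in cytosolic RNA from control to 16 h, while Tubb3 rose from 2.16 to 15.85 CPM. Others fell from low levels, so their folds are uncertain. Erg went from 3.16 to 0.135 CPM (24.5-fold) and Csf1r from 2.33 to 0.637 CPM (3.98-fold). Lyz2 went from 1.84 to 0.559 CPM (3.54-fold) and Tnnt2 from 5.80 to 1.94 CPM (3.24-fold). Epithelial, erythroid and adipocyte lists had fewer than 3 members in the tests, with Krt19 at up to 2.38 CPM and Fabp4 at up to 1.22 CPM. Of nuclear-retained RNAs 1 was held, Snhg11, at up to 6.62 CPM. P53 target genes were called in none of the 12 combinations either. Over all 396 list tests 174 were called with the preset correlation and 78 of these held with an estimated correlation. The median, the mean and the direction of the test differed in sign in 51 of the 396, none of which was called.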

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

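The tests of library slopes with GC content were chosen after the result was seen; the search for outlying libraries and the other splits of the samples were planned. In 3 of 120 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's ratio, where chance gives about 1 in 20 groups, or 6. Asns in control polysome RNA was 825.6 CPM in replicate 3 against 745 to 752.2 CPM in the others. Ddit3 in cytosolic RNA at 16 h was 417.4 CPM in replicate 1 against 499.9 to 509.1, and Herpud1 in polysome RNA at 16 h was 6285 CPM in replicate 2 against 6528 to 6570. Herpud1 at 1 h rose in cytosolic RNA (log2 change 1.09 ± 0.0416 SE) and fell in polysome RNA (-0.48 ± 0.0338), and the difference, tested as translational efficiency, was -1.64 ± 0.0508.

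Each count of called genes was compared over all ways of dividing its 8 samples 4 and 4, of which there are 35 with the real one included. In each of the 12 counts only 1 split, the real one, gave as many genes, the smallest share that 35 splits can give. This argues against a chance division of these samples but does not exclude it. The other splits mix conditions, which widens the spread within groups and lowers their counts where the conditions differ. The real counts ran from 3527 to 10273 by edgeR's quasi-likelihood test. The highest count of another split was 3618, for translational efficiency at 16 h against control, where the real split gave 8061. For the other 11 counts the highest of the other splits was 0.

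Libraries of 1 group differed from each other along the GC content of the transcripts, with Spearman's rho between a library's deviation from its group and GC content from -0.757 to 0.719. Depth as the cause is argued against by Pearson's r of 0.0294 between the slope and the log2 total over 32 libraries (95% interval -0.323 to 0.374; permutation p = 0.857). A state of the cells of a sample that both of its libraries share is neither shown nor excluded. Pearson's r between the slopes of the cytosolic and the polysome library of 16 samples was -0.061 (95% interval -0.54 to 0.448, permutation p = 0.868). This interval leaves a moderate relation possible. It is also too narrow, since it counts all samples as independent although the slopes are deviations from group means. Libraries with the same replicate number in different conditions had correlations of deviations from -0.477 to 0.649 in cytosolic RNA (median 0.016). In polysome RNA these ran from -0.391 to 0.488 (median -0.0156). The highest values joined control and 16 h, in replicate 1 (cytosolic) and replicate 3 (polysome). A batch common to some conditions was not tested. Differences between library preparations, single or shared, may remain, which the labels do not record, and no biological explanation was tested.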

How the results depend on the processing

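The GC and coding length corrections and the fit without 2 shallower samples at 1 h were chosen after the result was seen. Counts of called genes stayed within 1.5 times with DESeq2 size factors, library totals, no low-count filter, fits of only the conditions compared, and each sample left out in turn. With leave-one-out fits the count for translational efficiency at 16 h against 1 h ran from 2849 to 3703. The replicate number as a block moved no count by that factor. Counts that moved were all of translational efficiency: for 16 h against 1 h 5589 (GC correction), 1851 (without the shallower samples) and 7306 (analysis of partial variance) against 3527, and at 2-fold or more 71 (DESeq2) and 2894 (partial variance) against 35 higher and 78 lower; at 2-fold or more, 4890 at 16 h (partial variance) against 2886, and with the inhibitor 1023 (coding length correction) and 4151 (partial variance) against 1982. The correlations between comparisons moved when the shared samples were divided: inhibitor against 16 h to -0.617, -0.716 and -0.712 in cytosolic RNA, polysome RNA and translational efficiency, and 1 h against 16 h to 0.573 in polysome RNA and 0.834 in translational efficiency. With a mean of at least 10 CPM the polysome values were -0.762 and 0.661, and with leave-one-out fits inhibitor against 16 h in polysome RNA ran from -0.737 to -0.728. With fry, which tests a list against no change and not against the other genes, the direction turned for 3 lists that camera had not called (adjusted p = 0.934, 0.984 and 0.984). These were respiratory chain genes in cytosolic RNA at 16 h against 1 h (fry, adjusted p = 0.0325), and with the inhibitor p53 targets in polysome RNA (0.0083) and mitochondrial chaperones in translational efficiency (0.027). With the GC correction Dnajb9 turned to 0.0734 (cytosolic, 1 h) and 0.00854 (polysome, inhibitor). With the coding length correction the direction turned for ribosomal proteins in polysome RNA with the inhibitor (adjusted p = 0.92), Eif4g1 in cytosolic RNA at 16 h against 1 h (0.0694), Map2 in polysome RNA (-0.36 at 1 h, 0.14 with the inhibitor) and translational efficiency at 1 h (-0.15), Eif2ak3 in polysome RNA at 16 h (-0.37), and Atf3 and Xbp1 in translational efficiency at 16 h (0.040 and 0.015). The analysis of partial variance turned the most log2 changes of translational efficiency: at 1 h Asns 0.17, Atf3 0.31, Chac1 1.43, Trib3 0.19. At 16 h it gave Asns 0.57, Atf3 1.88, Chac1 2.55, Dnajb9 2.71, Eif2ak3 0.16, Herpud1 1.66, Trib3 0.79, Xbp1 0.88, Slc6a6 -0.69, Dnaja3 1.22, Ptgs2 -1.43, Sod2 0.054, Thbs1 -1.89, Csf1r -0.99, Tnnt2 -0.32. For 16 h against 1 h it gave Ddit3 1.46, Ppp1r15a 0.73, Inmt -5.35, Steap4 -3.77, Egr2 0.94, Nupr1 0.23, Aldh1l2 1.38, Edem1 1.39, Dad1 0.19, Stim1 -0.065, Vim -1.19, Atp5a1 -0.045, Hsd17b7 -0.42, Csf1 -1.18, Plk3 -0.77, Hspa8 -0.27, Map1lc3b 0.68, Map2 -0.38, Nes -1.64. With the inhibitor it gave Chac1 -4.02, Dnajb9 -0.46, Herpud1 -2.59, Trib3 -4.08, Xbp1 -0.68, Dusp1 2.72, Cyr61 0.097, Thbs1 0.62, Eng 0.37, Csf1r 0.17, Tnnt2 0.30. Its slope on cytosolic RNA was estimated from deviations of libraries within conditions. The median slope was -0.0255, with 6934 of 12561 genes under 0 and 41 over 1. Where the slope is near 0, the cytosolic change is hardly subtracted, and the value stays near the change in polysome RNA. Such a value is not a change in the ratio of polysome to cytosolic RNA. How far this accounts for each gene that turned was not tested. Libraries at 1 h were the shallowest, with 19.32 M counts at the lowest, and in simulated counts at their depths 72% of cytosolic changes of 0.5 on the log2 scale were called, against 56% for translational efficiency.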

Other observations

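The comparison of the inhibitor group with control was chosen after the data had been seen, as were the tests given here, except that of coding length for the list of mRNAs with upstream open reading frames, which was set before its result was seen. With the inhibitor, ER chaperones stayed above control in cytosolic RNA, with 21 of 25 higher and 2 lower (median log2 change 1.54; camera, adjusted p = 2.87e-27, and 0.000668 with an estimated correlation), among them Sdf2l1 (10.5-fold), Manf (9.77-fold) and Hspa5 (6.78-fold). ATF4 and CHOP target genes lay below control as a list, with 20 of 32 lower and 5 higher (median -0.412). For this list camera gave an adjusted p of 0.000892, and 0.00514 with an estimated correlation. Slc7a11 was 9.34-fold and Atf3 4.1-fold lower. Among the 5 higher, Ddit3 stayed 3.14-fold above control (2.87-fold in polysome RNA) and Ddit4 2.93-fold. Translational efficiency of ribosomal protein mRNAs was lower for 72 of 79 and higher for none (median -1.20; camera, adjusted p = 1.04e-72, and 0.000297 with an estimated correlation), and that of other TOP mRNAs for 17 of 19 (-0.912; camera, adjusted p = 6.6e-34, and 0.00356 with an estimated correlation). For ribosomal protein mRNAs this ratio held a rise in cytosolic RNA, with 75 of 79 higher and 1 lower (median 0.785). By camera that rise had an adjusted p of 3.84e-11, and 0.0302 with an estimated correlation. In polysome RNA 53 of 79 were lower and 1 higher (median -0.397). There camera gave an adjusted p of 0.0105, and 0.653 with an estimated correlation. Other TOP mRNAs had medians of 0.403 in cytosolic and -0.614 in polysome RNA. Translational efficiency of mRNAs with upstream open reading frames was not called (camera, adjusted p = 0.693), and that of Atf4 was 1.17-fold lower.

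Translational efficiency at 16 h rose for long coding sequences and fell for intermediate ones, with a difference in median log2 change of 1.23 between genes over 3000 nt and genes of 600 to 1500 nt. Abundance of the mRNA as the whole cause is argued against, since the difference was at least 0.809 ± 0.077 (SE) in each of 5 groups of genes by control level. Errors in this paragraph come from resampling genes and not from the fit, so they hold no spread between samples. GC content cannot be told apart as a part of the cause, since in the group of genes with the highest GC content, of 5, the difference was 0.627 ± 0.077, close to 0.5 of the overall value. Collection of mRNAs by ribosome number stays open: the median of the 600 to 1500 nt genes lay at -0.515 ± 0.031 relative to the genes under 400 nt, but this restates the medians in which the pattern was seen and does not support that explanation. With the inhibitor against 16 h alone, which shares the 16 h libraries, the median log2 change was -0.875 over 3000 nt. It was 0.388 for 600 to 900 nt and 0.16 for 900 to 1500 nt. A biological dependence on coding length stays open and was not tested.

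The list of mRNAs with upstream open reading frames rose in translational efficiency at 16 h. Coding length of its members as the cause is argued against, since with offsets corrected for coding length camera gave an adjusted p of 2.13e-09. Over the alternatives run for lists, by camera or fry, adjusted p ranged from 1.39e-11 to 0.0248. Lists were not tested with the analysis of partial variance, DESeq2's own test, no low-count filter or fits of only the conditions compared. Upstream ATGs as such may play a part, but the difference between genes with and without one changed sign with coding length. It was 0.185, 0.241 and 0.205 for coding sequences up to 600, of 600 to 900 and of 900 to 1500 nt. For 1500 to 3000 nt and over 3000 nt it was -0.0908 and -0.349. The mean of 0.0382 over the 5 bins cancels these differences and cannot decide the question, and no error was computed for them.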
